A study of Mus musculus with 2 samples.

How the data were processed

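Nuclei from snap-frozen gastrocnemius-plantaris muscle of mice with a mixed C57BL/6 and FVB background were released by detergent lysis and douncing, sorted on a nuclear pore antibody and used for a 10x Genomics assay of RNA and accessible chromatin, per the labels. There were 2 libraries, 1 control and 1 KIC, with 3 muscles of each group pooled before the assay per the labels' protocols. The series text names biological replicates, but nothing in the labels ties nuclei to animals, so each group is a single pool. Per the submitters' processing notes the data were made with Cell Ranger ARC 2.0.0 on the mm10 (GRCm38) genome, and Seurat 4.0.4 and Signac 1.4.0 are listed with no role given. The deposited matrices hold raw counts per nucleus: UMIs for 32285 genes and counts for the peaks of accessible chromatin, which were listed separately for each library. These deposited values are whole numbers and carry no normalization.

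Nuclei were kept with at least 300 genes and under 5% mitochondrial UMIs. This removed 275 and 110 nuclei under the gene minimum and 16 and 9 over the mitochondrial limit in control and KIC, some of them on both counts. Doublets were called per library with Scrublet in scanpy 1.11.5. Where the automatic threshold marked under 0.5%, the highest scores up to 0.8% per 1000 nuclei were taken instead. That rule applied to the control library (135 nuclei). The automatic threshold of 0.0678 applied to the KIC library (1198 nuclei). Kept nuclei had a median of 1601 and 1666 genes.

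Both libraries were clustered together without integration: scaling to 10000 UMIs, log1p, 2000 variable genes, 30 components, a shared-neighbour graph of 15 neighbours and Leiden clustering at resolution 0.5 with seed 0. Clusters were named from fixed markers of 19 cell types. For each marker the level in the library with more of the cluster's nuclei was set against the 10th percentile of the clusters of that library holding at least 20 nuclei, with 5 CPM added to both. The class with the highest median named the cluster when at least 3 of its markers were 2-fold up. A cluster stayed unnamed where a rival class reached 0.75 of the best median, or had as many or more markers among the 10 leading genes. This naming rule is the third version tried, and all versions were set after the clusters had been seen. Clusters named myofiber, neuromuscular junction or myotendinous junction together form the myofiber class. In alternative clusterings an unnamed cluster joined it where over 90% of its nuclei were in the class in the reported clustering, also set after seeing the data.

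UMIs were summed over the nuclei of a class in each library and scaled by the class total of that library, as CPM. The log2 ratio of KIC over control has an exact conditional binomial 95% interval for counting error. A group at 0 was set to a floor of 3 counts over the class. Gene lists (29, of which 6 are core lists) were read over members with at least 20 UMIs over both libraries. The median of a list has a binomial order-statistic interval over members, which for lists with under 6 members is the range and covers less than 95%. Its percentile comes from 10000 random lists whose members were drawn from the 100 genes nearest in mean CPM, and for the test of gene length, added after the files were seen, nearest in mean CPM and length. No p-value was computed, since each group has 1 library and nuclei are not replicates. Named genes in myofiber nuclei were the 12 highest and 12 lowest by the bound of the interval nearest to 0, among genes with at least 200 UMIs, leaving out mitochondrial, ribosomal protein, haemoglobin and sex chromosome genes and predicted genes (names beginning with Gm or ending in Rik). In cluster 2 they were the 5 highest and 5 lowest with at least 100 UMIs whose level was at least that in myofiber nuclei of the library in which they were higher. Members of the lists were named as examples, and the model genes first. Some items that these rules take are not reported here. The lists, markers, filters, rule for named genes and most alternatives were set before the data were examined.

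Shares of nuclei have exact Clopper-Pearson 95% intervals. For shares of nuclei with a UMI every nucleus was thinned to 1000 UMIs and shallower nuclei were left out. Endothelial-like nuclei were the fixed background, and cluster 2 was added after the data were seen because those nuclei were few. A leading myosin was called in nuclei with at least 2 UMIs of Myh1, Myh2, Myh4 and Myh7.

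Promoter counts were summed over myofiber nuclei from peaks within 1000 bp of the gene start that overlap a peak of the other library by at least 1 bp, and scaled to the counts in shared peaks. Gene positions came from the GENCODE vM21 annotation of GRCm38, which holds 32158 of the genes, since the feature files give no positions of genes. Peak counts were mostly even (84.3% and 88.0% of entries), so intervals were taken on half-counts. Promoters needed at least 40 counts, which left 15482. The position source, the half-counts and the minimum were chosen after the files were seen.

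The ratios and list medians were tested on simulated data. Counts were drawn for 13558 genes at the depth of the myofiber sums, with 200 changed. The intervals covered the true value for 96.0% of unchanged genes, and for 94.0%, 96.8% and 94.4% of 67, 62 and 71 genes changed by a log2 of 0.5, 1 and 2. Of 40 unchanged lists 39 fell in the middle 95% of random lists, and a list moved by a log2 of 1 lay at percentile 100. Counts were drawn independently for each gene with the counting error that the intervals assume. The simulation therefore checks the computation only. How members of a list vary together in real nuclei was not simulated.

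Alternatives were other filters (at least 1000 genes, no doublets removed), Leiden resolution 1.0, naming each nucleus by its highest marker mean, median-of-ratios scaling, the mean of per-nucleus CPM, thinning, nuclei led by Myh4 or Myh1, nuclei with an Xist UMI, members with at least 100 UMIs, at least 5 myosin UMIs, shares without thinning, peaks overlapping by 50% and promoters within 2000 bp. Added after the data were seen were a single doublet rule for both libraries (by threshold or by highest scores), the clusters shared by both libraries, leaving out the junction clusters, and taking out free RNA estimated from cluster 2. The last covered genes whose higher myofiber level was at least 5-fold above the KIC level in cluster 2. All their RNA in cluster 2 of each library was counted as free. This took out 8.69% of control and 0.957% of KIC myofiber UMIs. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.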

Results

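RNA and accessible chromatin were measured in the same single nuclei (10x Genomics multiome) of mouse gastrocnemius-plantaris muscle, a fast calf muscle group, at 66 days of age. The control mice carried floxed Ink4a alleles. The KIC mice also carried further alleles, among them a Cre recombinase under Ptf1a, a gene of pancreatic progenitors, and serve as a model of pancreatic cancer cachexia, the wasting of muscle and fat in cancer. The question was how the nuclei of wasting muscle differ from those of control muscle. Each group gave 1 library made from 3 pooled muscles. The series text speaks of biological replicates, but no label ties a nucleus to an animal, so there was no replicate check and no test between the groups. Differences are described as ratios between these 2 libraries, and every interval, given in brackets or parentheses, is a 95% interval for counting error only, except that a list median carries an interval over its members.

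The control library held 4398 nuclei with 24927158 RNA molecules counted by UMI, and the KIC library held 5640 nuclei with 31244746. After filters and doublet removal 3978 and 4330 nuclei remained, with a median of 3632 and 3750 UMIs. Doublet removal acted unequally: it took 3.28% of the control and 21.7% of the KIC nuclei. Genes of the model were checked first. Neither library held a Cdkn2a or Ptf1a UMI in myofiber nuclei, which allows up to 0.283 CPM in the control and 0.188 CPM in the KIC library. Both libraries held Xist RNA (1709 and 2141 CPM over all kept nuclei) and few Y-linked UMIs (5 and 4). Of the sex chromosome genes, Xist and Tsix were measured in myofiber nuclei, with log2 ratios of KIC over control CPM of 0.53 and 0.60. Tsix overlaps Xist on the opposite strand, so its count is uncertain.

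Myofiber-like nuclei, called myofiber nuclei from here on, made up 55.3% (53.7 to 56.9) of the kept control nuclei and 78.8% (77.6 to 80.1) of the kept KIC nuclei. They were the nuclei of clusters with Ttn, Neb, Ckm and other contractile genes, including a myotendinous junction-like cluster with Col22a1 and a neuromuscular junction-like cluster with Colq. Pericyte-like or smooth muscle-like nuclei with Myh11 and Rgs5 were 3.80% (3.22 to 4.44) and 0.785% (0.544 to 1.10). Satellite cell-like nuclei with Pax7, the muscle stem cells, were 0.905% (0.635 to 1.25) and 1.06% (0.779 to 1.41), and endothelial-like nuclei with Pecam1 were 0.503% (0.307 to 0.775) and 0.162% (0.0650 to 0.333). Clusters left unnamed held 39.5% and 19.1%. Among them were clusters 2 and 9, both with fibro-adipogenic progenitor markers. Another held F13a1 and Mrc1 of macrophages beside Reln and Mmrn1 of lymphatic endothelium, and another held adipocyte genes beside slow myosin Myh7. All these shares depend on the naming and filter rules. With at least 1000 genes the pericyte-like or smooth muscle-like shares were 0.442% and 0.133% and the satellite cell-like shares 0.442% and 0.320%. Naming each nucleus by its highest marker mean gave 1.58% and 0.762% for pericyte-like or smooth muscle-like, 0.503% and 0.993% for satellite cell-like and 0.628% and 0.577% for endothelial-like nuclei, and resolution 1.0 gave 1.23% and 0.577% for the last. For myofiber nuclei the highest marker mean gave 77.9% and 79.8% in control and KIC, so most of the gap closed under that rule. The nuclei had been sorted with a nuclear pore antibody, so shares of loaded nuclei are not shares of the tissue.

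The myofiber class held 2200 control nuclei with 10588705 UMIs (median 3855) and 3414 KIC nuclei with 15985598 UMIs (median 4222). Different clusters made up most of it in each library. Cluster 1 held 1220 of the control nuclei and 68 KIC nuclei. Clusters 3, 4 and 6 held 1122, 967 and 650 KIC nuclei and 1, 1 and 49 control nuclei. Only clusters 5 and 7 held at least 100 nuclei of both (790 control and 492 KIC nuclei together). Their nuclei were summed in unequal parts: 354 control and 380 KIC nuclei in cluster 5, and 436 and 112 in cluster 7. Cluster 5 was led by Myh2 and Myh1 among others, so values for clusters 5 and 7 together also compare mixtures. Every myofiber ratio compares these mixtures, and with a single library per group the kind of nucleus and the library could not be separated for clusters 1, 3, 4 and 6. Over the 13558 genes with at least 20 UMIs the median log2 ratio was 0.27. Values are given as CPM ratios, and values relative to the shift are taken against the median-of-ratios shift of 0.27. Signs of other cells and of handling differed too. In myofiber nuclei the collagen and matrix list had a median of -0.76 [-1.88 to 2.51] (0.37 without the junction clusters), the endothelial gene Flt1 stood at -4.18 [-6.52 to -2.52], and mitochondrial RNA made up a mean of 0.155% and 0.0566% of UMIs over all kept nuclei.

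Genes that respond to loss of nerve contact were higher in KIC myofiber nuclei. Among them were Sln, a regulator of the sarcoplasmic calcium pump (1.89 and 216 CPM in control and KIC, log2 ratio 6.84 [6.21 to 7.55]), the transcription factor Runx1 (8.31 and 483 CPM, 5.86 [5.56 to 6.18]), Gadd45a (4.63 and 158 CPM, 5.09 [4.68 to 5.53]) and the adhesion molecule Ncam1 (46.7 and 514 CPM, 3.46 [3.33 to 3.59]). Myog, a myogenic factor that returns after denervation (3.21 and 25.3 CPM, 2.98 [2.47 to 3.53]), and the acetylcholine receptor subunit gene Chrna1 (1.13 and 15.6 CPM, 3.79 [2.96 to 4.76]) were higher as well. Of 14 measured members of the list, 13 had an interval above 0 and 1 below it, Hdac4 at -0.17 [-0.22 to -0.12], and these counts were 13 and 1 relative to the shift. The list median was 3.62 [1.18 to 5.25], or 3.36 relative to the shift, at percentile 100 of 10000 random lists matched on mean CPM. The fetal and gamma-subunit members were scarce. Chrng had 0 control and 74 KIC UMIs, 16.3-fold higher with the control set to a floor of 3 counts. Myh8 was under the minimum, and Myh3 had no KIC UMI. In clusters 5 and 7 alone the median was 1.83. Levels differed between KIC clusters, a split made after the results were seen. In KIC nuclei of clusters 3 and 6 (1122 and 650 of 3414) Ncam1 stood at 6.73 and 3.31 CPM, under control. Myog was under control there too, at 1.55 and 1.10 CPM. Runx1 (68.6 and 5.15 CPM) was under control only in cluster 6, and Gadd45a (22.5 and 9.56 CPM) in neither. KIC nuclei of clusters 4 and 5 (967 and 380) were above control for all of these genes, although Myog in cluster 5 stood at only 4.26 CPM. Control here means the whole control myofiber class. These cluster levels carry no interval, so small differences from control may be counting error.

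Ubiquitin ligases of muscle atrophy were higher in the KIC library for the best known members and not for the list as a whole. Trim63, which encodes MuRF1 (ENSMUSG00000028834, chromosome 4, 134315120 to 134329629, GRCm38), had 1699 and 6031 CPM in control and KIC, a log2 ratio of 1.83 [1.80 to 1.85]. Fbxo32, which encodes atrogin-1 (ENSMUSG00000022358, chromosome 15, 58175879 to 58214932), had 1406 and 5825 CPM, a log2 ratio of 2.05 [2.03 to 2.08]. Fbxo30 (1.55 [1.34 to 1.76]) and Mdm2 (1.32 [1.18 to 1.45]) were also higher, while Asb2 (-1.22 [-1.26 to -1.19]) and Stub1 (-1.50 [-1.71 to -1.29]) were lower. Of 16 members 10 were higher and 3 lower, or 8 and 5 relative to the shift. The median of 0.41 [-0.23 to 1.32] lay at percentile 96.0, and its interval includes 0.

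The protein breakdown machinery beyond the ligases was higher more evenly. All 31 proteasome subunit genes had intervals above 0, from Psmb7 at 0.43 [0.33 to 0.54] to Psmd8 at 1.77 [1.42 to 2.14], and 30 of them were also above the shift. Their median was 1.12 [0.87 to 1.26] at percentile 100. Of 16 autophagy and lysosome genes 13 were higher and 1 lower (9 and 2 relative to the shift), with a median of 0.70 [0.23 to 1.44] at percentile 99.6. Gabarapl1 (2.42 [2.15 to 2.70]), Map1lc3b (1.77 [1.56 to 1.99]) and the cargo receptor gene Sqstm1 (1.44 [1.33 to 1.55]) were among the higher ones, and Tfeb (-0.81 [-0.91 to -0.70]), a regulator of lysosomal genes, was the lower one. Of 12 FoxO factors and targets 9 were higher and 2 lower (8 and 3 relative to the shift), with a median of 0.76 [0.16 to 1.45] at percentile 99.8. The lysosomal protease gene Ctsl (4.21 [3.95 to 4.49]) and the translation repressor gene Eif4ebp1 (2.43 [2.15 to 2.72]) were higher, and Foxo1 itself (-0.47 [-0.50 to -0.44]) was lower.

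**Figure D1:**
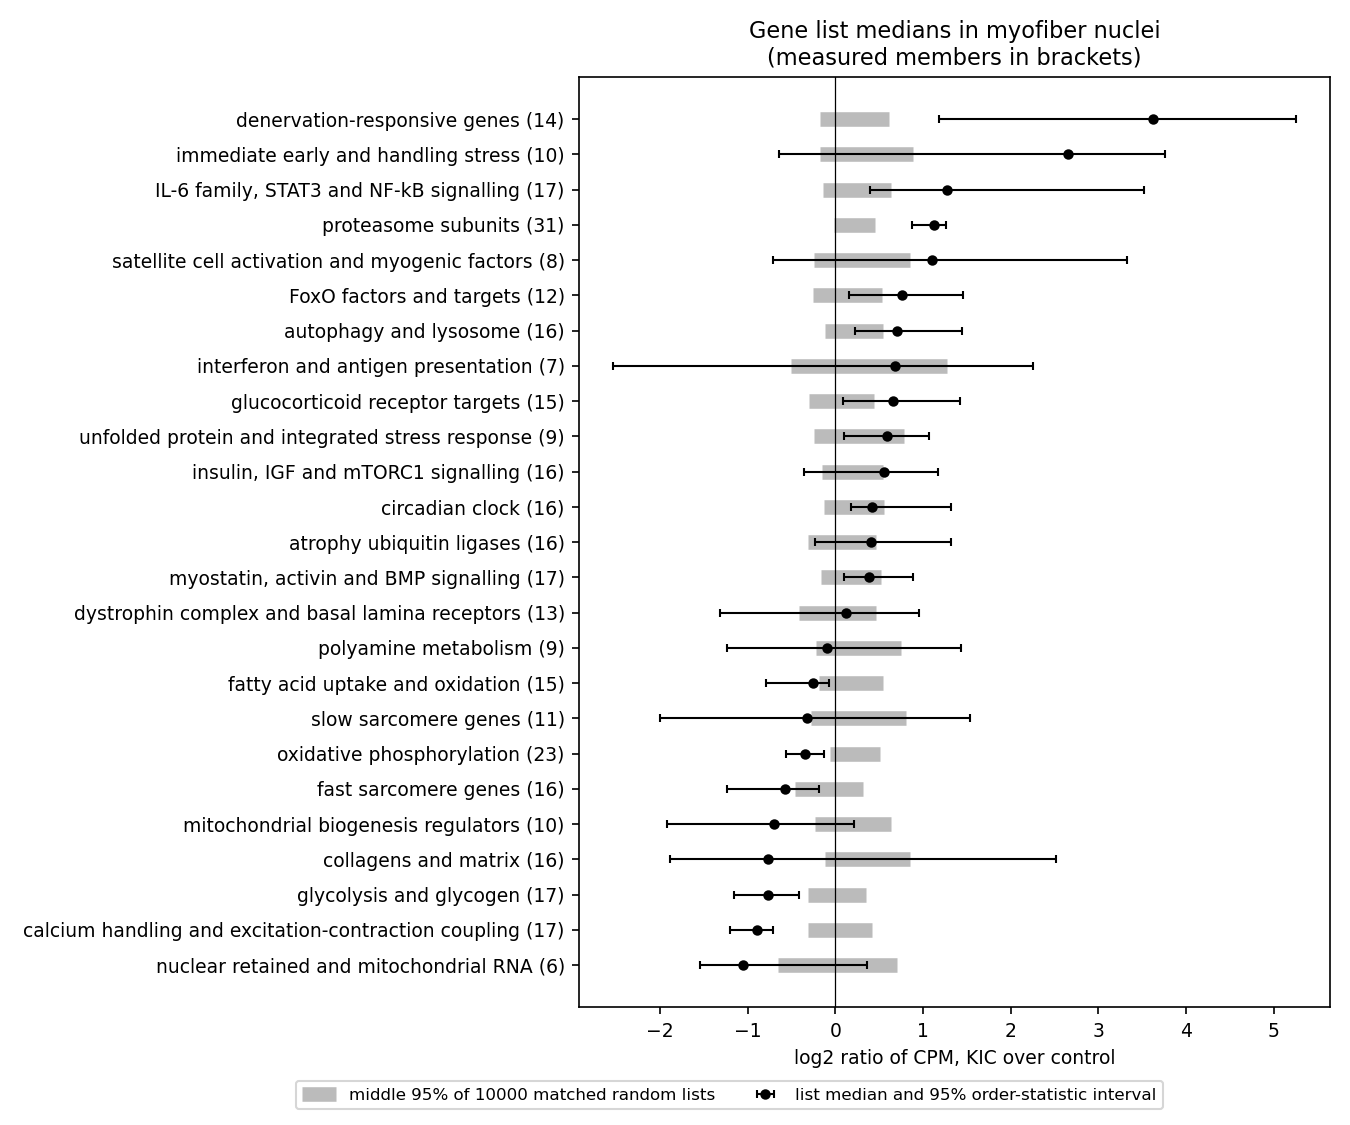
Median log2 ratio of CPM, KIC over control, of each gene list in myofiber nuclei (points), with the 95% order-statistic interval over members (lines) and the middle 95% of 10000 random lists matched on mean CPM (grey). Lists with fewer than 6 measured members are left out. The denervation-responsive genes sit at 3.62, proteasome subunits at 1.12 and calcium handling genes at -0.89, each outside the grey range.

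Glucocorticoid receptor targets were mostly higher, although well known targets were lower. The metallothionein genes Mt2 (2.62 [2.41 to 2.83]) and Mt1 (2.42 [2.22 to 2.61]), Errfi1 (2.15 [2.01 to 2.30]) and Pik3r1 (1.42 [1.37 to 1.47]), a regulatory subunit of PI3-kinase, were higher. Fkbp5 (1362 and 835 CPM, -0.71 [-0.74 to -0.67]), Zbtb16 (4517 and 2016 CPM, -1.16 [-1.18 to -1.14]) and Dusp1 (-0.89 [-1.08 to -0.71]) were lower. Of 15 members 12 were higher and 3 lower, or 10 and 5 relative to the shift. The median was 0.65 [0.081 to 1.42], 0.39 relative to the shift, at percentile 99.9.

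In the myostatin, activin and BMP list the ligand Mstn, a brake on muscle growth, was lower (35.7 and 15.7 CPM, -1.18 [-1.42 to -0.95]), while the BMP target Id1 (4.70 [3.70 to 5.92]) and the ligand trap Fst (3.69 [3.18 to 4.24]) were higher. Smad3 (-0.75 [-0.84 to -0.66]) was lower and Smad7 (0.89 [0.69 to 1.09]) higher. Of 17 members 12 were higher and 3 lower, or 8 and 5 relative to the shift. The median of 0.38 [0.093 to 0.89] lay at percentile 87.6, inside the middle 95% of random lists, and was 0.11 relative to the shift.

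Contractile, calcium handling and glycolytic RNA was lower in KIC myofiber nuclei. Of 16 fast sarcomere genes 13 were lower and 2 higher. Mybpc2, the fast myosin binding protein C (589 and 86.1 CPM, -2.78 [-2.86 to -2.69]), Ckm, the muscle creatine kinase (804 and 258 CPM, -1.64 [-1.69 to -1.59]), and the fastest myosin Myh4 (3680.1 and 1578 CPM, -1.22 [-1.24 to -1.20]) were lower, and the light chain genes Myl1 (0.73 [0.69 to 0.78]) and Mylpf (0.57 [0.49 to 0.66]) were higher. Of 17 calcium handling and excitation-contraction coupling genes 15 were lower, among them the release channel gene Ryr1 (2707 and 1065 CPM, -1.35 [-1.37 to -1.32]) and the calcium buffer gene Pvalb (-1.48 [-1.56 to -1.41]), against a higher Cacng1 (2.51 [2.38 to 2.65]) and Cacnb1 (0.58 [0.36 to 0.80]). Of 17 glycolysis and glycogen genes 14 were lower and 2 higher, with the glycogen phosphorylase gene Pygm at -1.59 [-1.64 to -1.55], the phosphorylase kinase gene Phka1 at -1.56 [-1.59 to -1.54] and the branching enzyme gene Gbe1 at 0.48 [0.44 to 0.51].

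The medians were -0.57 [-1.24 to -0.19] for fast sarcomere genes at percentile 0.690, -0.89 [-1.21 to -0.71] for calcium handling at percentile 0.0100 and -0.77 [-1.16 to -0.42] for glycolysis at percentile 0. Relative to the shift they were -0.84, -1.16 and -1.04, with 14, 15 and 15 members lower. The medians differed between subsets. Fast sarcomere genes stood at 0.19 in nuclei led by Myh1 and -0.19 in clusters 5 and 7, and calcium handling genes at -0.039 and -0.35. Calling a leading myosin left out 1832 of 3414 KIC but 124 of 2200 control nuclei with under 2 adult myosin UMIs. Myh1 is also on the fast sarcomere list, so nuclei led by Myh1 cannot decide whether the direction varies. Fast sarcomere RNA also reached control nuclei of cluster 2 in larger amounts than KIC nuclei of that cluster. The slow sarcomere list, with Myh7 at -4.04 [-5.21 to -3.06] and Tnnt1 at 1.80 [1.10 to 2.57], had a median of -0.32 [-2.005 to 1.53] at percentile 2.08. Cluster 12, led by Myh7 beside adipocyte genes, is not part of the class, and the slow median was 1.31 in clusters 5 and 7.

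Mitochondrial genes were mostly lower in KIC myofiber nuclei. Of 23 oxidative phosphorylation genes 15 were lower and 1 was higher, or 21 and 1 relative to the shift. Sdhc (-0.85 [-0.95 to -0.74]), Cox5a (-0.75 [-0.90 to -0.61]) and Atp5o (-0.95 [-1.27 to -0.64]) were among the lower ones, and the muscle isoform gene Cox6a2 (1.27 [1.02 to 1.52]) was the higher one. The median was -0.34 [-0.56 to -0.13] at percentile 0.0100, -0.61 relative to the shift, and -0.051 in clusters 5 and 7 alone. Of 10 regulators of mitochondrial biogenesis 6 were lower and 2 higher, with Ppara at -2.30 [-2.41 to -2.19], Esrrg at -1.93 [-1.97 to -1.88], Ppargc1a at -0.74 [-0.80 to -0.68] and a median of -0.70 [-1.93 to 0.21] at percentile 0. Of 15 fatty acid genes 10 were lower and 2 higher, with Ucp3 at -1.36 [-1.43 to -1.29], the lipase gene Pnpla2 at 1.53 [1.26 to 1.80] and a median of -0.26 [-0.79 to -0.070] at percentile 1.19, which was 0.082 in clusters 5 and 7. Mitochondrially encoded RNA was lower, with mt-Nd4 at -1.54 [-1.86 to -1.23], while nuclear Malat1 was at 0.36 [0.36 to 0.37]. Mitochondrially encoded RNA is listed above among signs of handling, so its difference could not be separated from the preparation of the nuclei. The nuclear retained and mitochondrial list of 6 genes had a median of -1.06 [-1.54 to 0.36] at percentile 0.360.

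Cytokine signalling genes were higher in KIC myofiber nuclei. Serpina3n, an acute-phase serine protease inhibitor, had 1 and 318 UMIs in control and KIC (log2 ratio 7.72 [5.23 to 13.03]), and the oncostatin M receptor gene Osmr had 7 and 275 (4.70 [3.64 to 6.03]). Stat3 (1.28 [1.17 to 1.38]) and Il6ra (1.71 [1.59 to 1.83]) were higher, and Lifr (-1.47 [-1.63 to -1.31]) was lower. Of 17 members of the IL-6 family, STAT3 and NF-kB list 14 were higher and 3 lower (11 and 4 relative to the shift), with a median of 1.28 [0.40 to 3.52] at percentile 100, and of 0.44 in clusters 5 and 7. Of 16 members measured in cluster 2, 14 were at or above the myofiber level there in both libraries. Whether RNA of other cells in myofiber nuclei adds to these ratios was not tested for this list. Immediate early genes, which also respond to tissue handling, were higher beside this list: 8 of 10 were higher, with Junb at 3.76 [3.18 to 4.40] and Atf3 at 3.64 [3.01 to 4.35], and the median was 2.65 [-0.64 to 3.76]. The interferon list had 7 of 17 members measured, 4 higher and 3 lower, with H2-K1 at 2.25 [1.59 to 2.99], Gbp7 at -2.53 [-4.12 to -1.20] and a median of 0.68 [-2.53 to 2.25] at percentile 77.7. Serpina3n, H2-K1 and Gbp7 belong to families with close copies, so their counts are uncertain.

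The 24 genes farthest from equal by the bound nearest to 0 were named by a rule of size. The 12 higher in KIC were Frmd5, Kcnk5, Enpp3, Sln, Hhipl1, Ankrd1, Sh3d19, Pakap, Pxdn, Serinc5, Runx1 and Hamp2. Frmd5 (ENSMUSG00000027238, chromosome 2, 121545529 to 121807087) had 23 and 7303 UMIs and a log2 ratio of 7.72 [7.13 to 8.38]. The potassium channel gene Kcnk5 had 6 and 2530 UMIs (8.13 [7.002 to 9.57]), the ectoenzyme gene Enpp3 5 and 2182 (8.18 [6.95 to 9.80]), and Ankrd1, a titin-binding stress protein, 19 and 3044 (6.73 [6.08 to 7.46]). Hamp2, of the hepcidin family, had 0 control and 255 KIC UMIs, and has a close copy in Hamp. It was 56.3-fold higher with the control set to a floor of 3 counts in the class. The others lay between 5.86 (Runx1) and 7.09 (Pxdn).

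Among the 12 lower in KIC were Rasgrp2, Tafa4, Pebp4, Map2k6, Foxo6, Kcnh7, Adamtsl1, Sox2ot, Clstn2, Igfbp5 and Gdap1. Rasgrp2, an exchange factor for Rap (ENSMUSG00000032946, chromosome 19, 6399340 to 6415216), had 225 and 12 UMIs (-4.82 [-5.80 to -3.99]). The p38 kinase kinase gene Map2k6 had 2823 and 301 (-3.82 [-4.00 to -3.65]), Adamtsl1 9794 and 1358 (-3.44 [-3.53 to -3.36]) and the IGF binding protein gene Igfbp5 988 and 137 (-3.44 [-3.71 to -3.19]). All 24 kept their direction relative to the shift. Frmd5, Enpp3, Sln, Hhipl1 and Pakap are among the 10 leading genes of cluster 4, Pebp4 and Gdap1 of cluster 1, Kcnh7 and Clstn2 of the myotendinous cluster and Tafa4 of the neuromuscular cluster. Without the junction clusters Kcnh7 stood at -0.26 and Tafa4 gave no value, and in clusters 5 and 7 Clstn2 stood at 0.53.

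**Figure D2:**
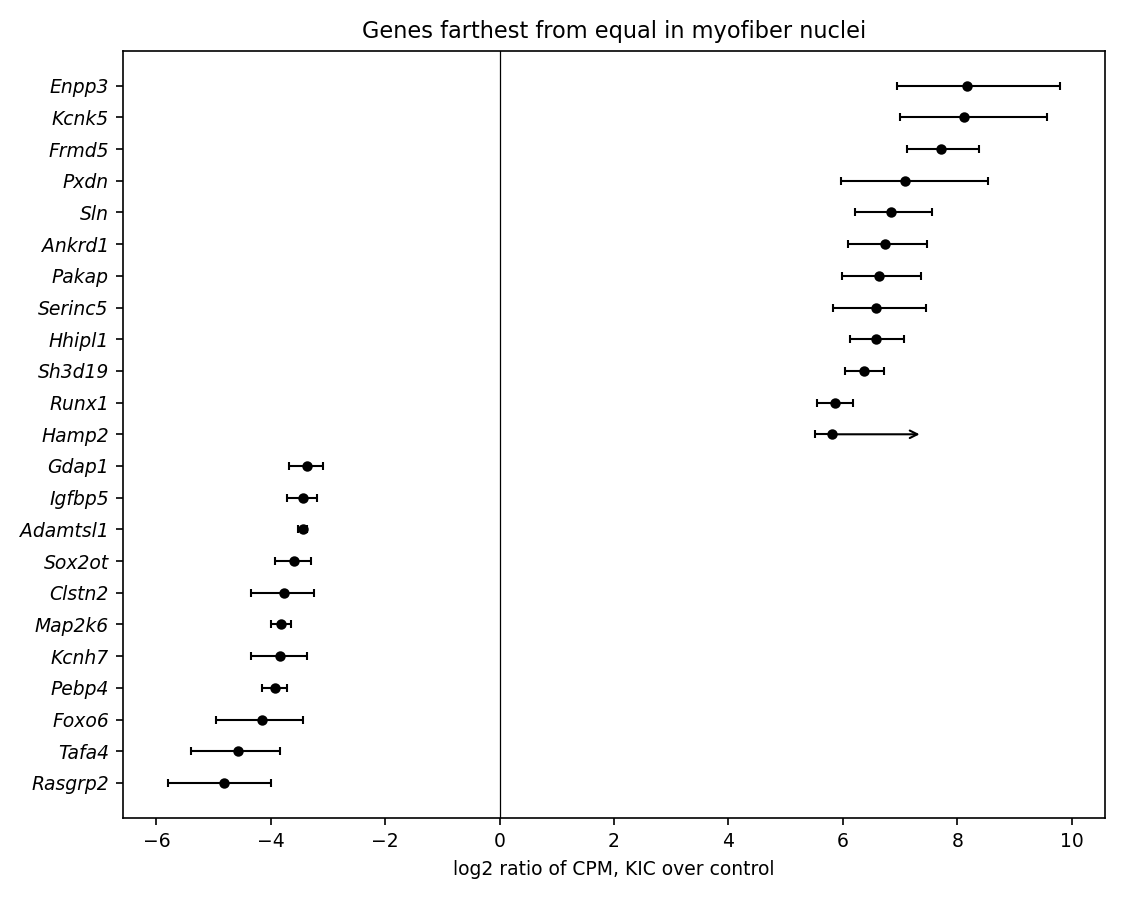
Log2 ratio of CPM, KIC over control, of the genes named here in myofiber nuclei, with 95% counting intervals (lines). The arrow marks Hamp2, which had 0 control UMIs, so its value rests on a floor of 3 counts and its interval has no upper end. The higher genes run from Hamp2 at 5.82 to 8.18 and the lower ones from -4.82 to -3.37.

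Adult myosin genes were read per nucleus. Among myofiber nuclei with at least 2 UMIs of Myh1, Myh2, Myh4 and Myh7, Myh4 led in 81.8% (80.0 to 83.4) of control and 74.7% (72.4 to 76.8) of KIC nuclei, Myh1 in 10.9% (9.55 to 12.3) and 16.4% (14.6 to 18.3), and Myh2 in 7.11% (6.04 to 8.31) and 8.85% (7.48 to 10.4). Myh7 led in 5 and 1 nuclei. These shares leave out 124 of 2200 control nuclei and 1832 of 3414 KIC nuclei with fewer myosin UMIs, and 23 and 22 ties. With every nucleus thinned to 1000 UMIs, 5.85% (4.86 to 6.97) of control and 56.6% (55.0 to 58.3) of KIC myofiber nuclei held no adult myosin UMI. The leading myosin is a count per nucleus, not a fiber type call.

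Runx1, Ncam1, Trim63 and Fbxo32 each had a UMI in a larger share of KIC than of control myofiber nuclei at equal depth. Such shares depend on depth, and a nucleus without a UMI may still express the gene. With every nucleus thinned to 1000 UMIs (leaving out 216 and 51 shallower ones), a Runx1 UMI was present in 0.655% (0.349 to 1.12) of control and 18.8% (17.5 to 20.2) of KIC nuclei, and a Ncam1 UMI in 1.51% (1.02 to 2.15) and 18.4% (17.1 to 19.8). For Myog the shares were 0.202% and 1.398%, for Chrna1 0.151% and 0.952%, and for Mstn 3.43% and 1.398%. Trim63 was present in 65.5% (63.4 to 67.6) and 85.4% (84.2 to 86.6), and Fbxo32 in 57.7% (55.5 to 59.8) and 87.6% (86.5 to 88.7). Without thinning the shares were 2.86% and 31.7% for Runx1, 3.59% and 27.7% for Ncam1, 1.32% and 7.06% for Myog, 0.545% and 5.04% for Chrna1, 11.6% and 5.21% for Mstn, 85.6% and 97.3% for Trim63, and 79.7% and 94.96% for Fbxo32.

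Endothelial-like nuclei, the background fixed for these shares, numbered only 18 and 7 after thinning (median 2424 and 2810 UMIs before it). None held Myog, Chrna1, Runx1, Ncam1 or Mstn, which allows a share of up to 16.7% and 42.9%. Trim63 was present in 5.56% of the control ones and Fbxo32 in 16.7%, and neither in the KIC ones. Cluster 2 was added as a larger background (518 and 486 nuclei, median 2488 and 2041 UMIs before thinning). There Myog and Chrna1 were in no nucleus of either library, allowing up to 0.579% and 0.617%. Trim63 was in 14.1% and 7.61%, Fbxo32 in 14.5% and 10.7%, and Mstn in 0.193% of control and no KIC nuclei. Runx1 was in 2.70% and 6.17% and Ncam1 in 9.07% and 3.91%, and the control myofiber shares of Runx1, Ncam1, Myog and Chrna1 were at or under the level in cluster 2 or the limit a count of 0 allows there. The KIC shares of all 7 genes were above it.

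**Figure D3:**
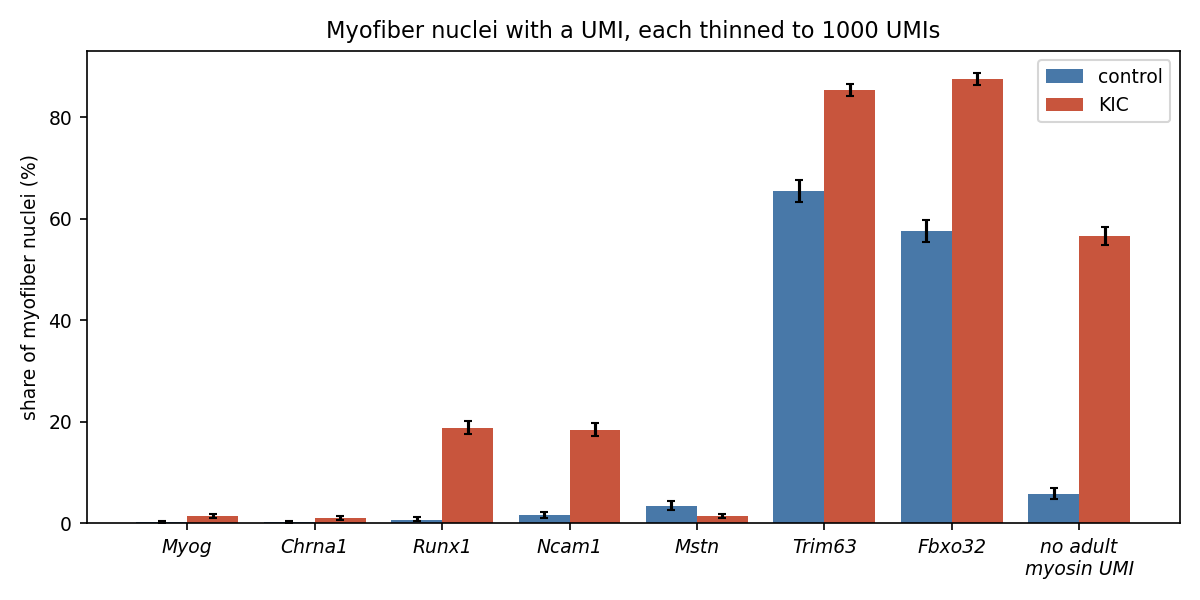
Share of myofiber nuclei (%) with at least 1 UMI of each gene, and with no adult myosin UMI, in the control and KIC library, each nucleus thinned to 1000 UMIs. Bars are shares and lines are exact 95% binomial intervals for counting error. Runx1 stands at 18.8% and Ncam1 at 18.4% of KIC nuclei.

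Promoter accessibility differed in the same direction as RNA for several of these genes, by smaller amounts. The Trim63 promoter had a log2 ratio of 0.55 [0.37 to 0.74] in KIC over control myofiber nuclei, Fbxo32 0.40 [0.25 to 0.56], Ncam1 1.09 [0.59 to 1.62], Chrna1 1.599 [1.20 to 2.01] and Ankrd1 1.67 [1.31 to 2.06]. The Mybpc2 promoter was at -1.21 [-1.36 to -1.05], Myh4 at -0.66 [-0.87 to -0.44] and Mstn at -0.75 [-1.19 to -0.30]. Myog (0.087 [-0.13 to 0.31]) and Gadd45a (0.090 [-0.069 to 0.25]) promoters had intervals that include 0. So did those of Ckm (-0.044 [-0.27 to 0.19]) and Pygm (-0.038 [-0.17 to 0.097]), whose RNA was lower. The Ttn promoter was higher at 0.28 [0.13 to 0.43], against its RNA (47158 and 26812 CPM in control and KIC). Of the 12 genes named as higher, 11 had a measured promoter and 9 of these were above 0, 4 with their whole interval, while Pakap was below 0 with its whole interval. Of the 12 named as lower, 8 had a promoter and 7 of these were below 0, 3 with their whole interval.

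By list, the median promoter log2 ratio was 0.23 [-0.14 to 1.09] for denervation-responsive genes (percentile 99.5 among matched random lists of promoters), -0.11 [-0.66 to 0.053] for fast sarcomere genes (percentile 0.200), 0.032 [-0.094 to 0.062] for oxidative phosphorylation (percentile 61.4) and 0.029 [-0.10 to 0.32] for glucocorticoid targets (percentile 39.2). It was -0.019 [-0.23 to 0.19] for atrophy ligases (percentile 19.2) and -0.055 [-0.18 to 0.059] for the myostatin, activin and BMP list (percentile 15.6). Proteasome subunit promoters were at 0.22 [0.14 to 0.26] (percentile 100) and calcium handling promoters at -0.24 [-0.55 to 0.043] (percentile 0). Glycolysis promoters, at 0.023 [-0.32 to 0.14], lay at percentile 32.8. Peaks were listed separately for each library, so only peaks overlapping between the libraries were used (66944 of 83521 control and 67019 of 89350 KIC peaks).

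**Figure D4:**
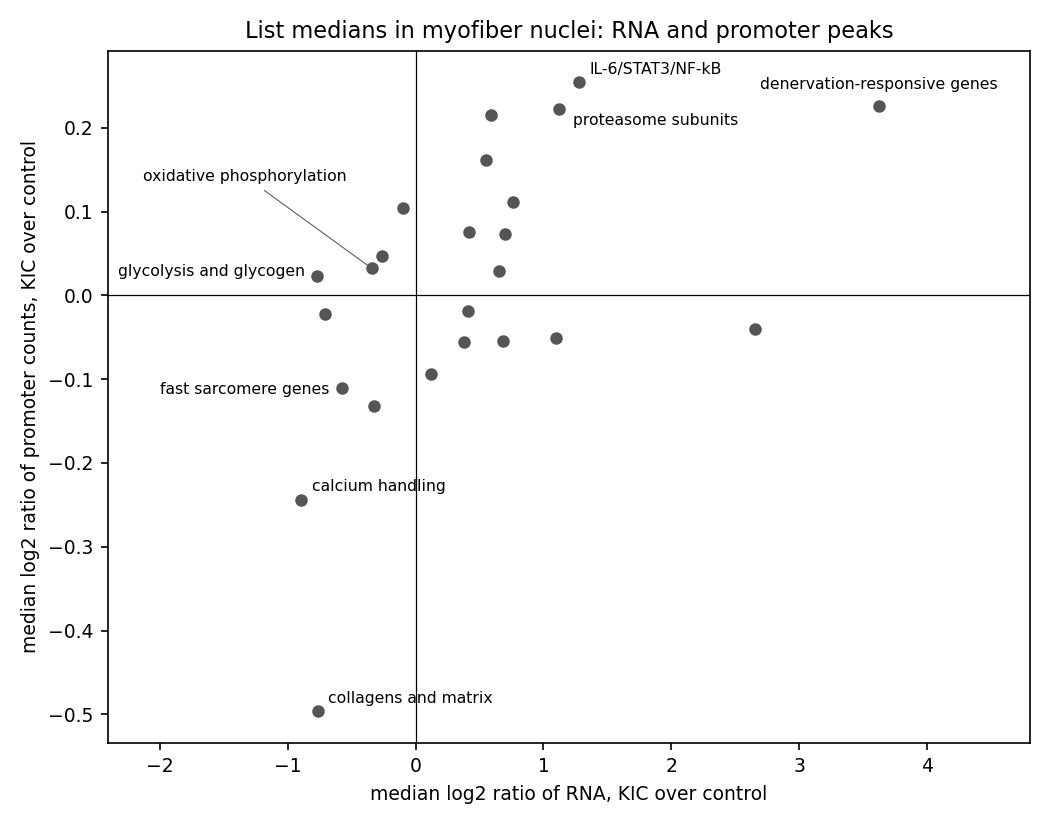
Median log2 ratio of promoter counts (vertical axis) against median log2 ratio of RNA (horizontal axis), KIC over control, in myofiber nuclei, for gene lists with at least 6 members measured for RNA (points; some are labelled). Denervation-responsive genes stand at 3.62 for RNA and 0.23 for promoters, and glycolysis genes at -0.77 and 0.023.

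In the reported clustering no named class other than myofiber held 100 nuclei in each library. Cluster 2 was compared instead, a choice made after the clusters were seen. Other settings named a fibro-adipogenic progenitor class, which as a whole was not compared. It held 640 control and 611 KIC nuclei (16.1% and 14.1%) at resolution 1.0, and 107 and 55 with a single score threshold. Cluster 2 held 616 control and 560 KIC nuclei. All 10 fibro-adipogenic progenitor markers were raised in it, but Scn7a of the Schwann cell list was among its leading genes, so it stays unnamed. Cluster 8 also held over 100 nuclei of each library but mixes cell types and was not compared. Cluster 9 (382 control and 77 KIC nuclei) also had all 10 progenitor markers raised. A part of the nuclei with these markers, mostly from the control library, thus lies outside the comparison. The chemokine gene Cxcl13 had 0 control and 147 KIC UMIs, 79.8-fold higher with the control set to a floor of 3 counts. Igfbp3 (20.3 and 698 CPM, log2 ratio 5.11 [4.68 to 5.57]), the complement gene C4b (4.40 and 123 CPM), Junb (4.57 [3.60 to 5.73]) and the collagen crosslinking enzyme gene Lox (3.33 [2.83 to 3.88]) were higher. Adamtsl2 (-4.86 [-7.16 to -3.28]), Ano4 (-3.32 [-4.67 to -2.23]), Nrep (-2.30 [-3.15 to -1.54]), Col15a1 (289 and 63.2 CPM, -2.19 [-2.53 to -1.87]) and Col5a3 (-2.09 [-2.38 to -1.82]) were lower. The median-of-ratios shift in cluster 2 was 0.089.

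Lists in cluster 2 were read over all measured members, including those higher in myofiber nuclei. Of 16 IL-6 family, STAT3 and NF-kB genes 12 were higher and none lower (median 1.17 [0.44 to 2.24]). Of 20 collagen and matrix genes 13 were lower and 5 higher (median -0.40 [-0.84 to -0.0028]), with Col3a1 at -0.84 [-0.96 to -0.71] and Dcn at 1.06 [0.996 to 1.12]. Of 8 immediate early genes 6 were higher and 1 lower (median 1.79 [-1.15 to 4.95]). Of 9 measured interferon and antigen presentation genes (17 listed) 5 were higher and none lower (median 0.80). Control nuclei of cluster 2 also held myofiber RNA that KIC nuclei largely lacked: Ttn was at 14483 CPM in control and 330.1 CPM in KIC, or 30.7% and 1.23% of the level in myofiber nuclei of the same library.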

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

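The test of free RNA by the median nucleus of cluster 2 was chosen only after a first test of that explanation had been seen. All other tests here were set before their results were seen.

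A signal lay in data the comparisons do not use: peaks of the KIC library that overlap no control peak held 9.51% of the peak counts over all its nuclei, against 6.17% for control peaks that overlap no KIC peak.

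Fast sarcomere, glycolysis and calcium handling RNA was lower in KIC myofiber nuclei (median log2 ratio -0.79 [-1.07 to -0.57] over 50 genes). For free myofiber RNA in the control library, the first test took all myofiber RNA of cluster 2 out and left -0.59 [-0.84 to -0.25], which met neither of the bounds set for it, so free RNA may add to the size. The interval around -0.59 is over members and holds no error of the amount taken out. It therefore cannot decide whether free RNA is the whole cause. In the replacing test cluster 2 control nuclei held on average 52.3% of the UMIs by which a control myofiber nucleus exceeds the KIC level. That is past the 50% bound set for the median nucleus, which itself held only 2.58%. Nuclei above the median thus held nearly all of this RNA. Gene length is argued against by a percentile of 0 among random lists matched on mean CPM and gene length. Less open promoters of these genes in the KIC library stay open as a candidate explanation for the fast sarcomere and calcium handling genes (promoter percentiles 0.200 and 0) but not for the glycolysis genes, whose promoter median was 0.023 [-0.32 to 0.14] at percentile 32.8, and all 3 lists pooled lay at percentile 0 of random promoter lists, with a promoter median of -0.10 [-0.31 to -0.0069] that is much nearer to 0 than the RNA median. Disease and library could not be separated with a single pool per group.

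Denervation-responsive RNA was higher in KIC myofiber nuclei (median 3.62 [1.18 to 5.25]). More junction nuclei in the KIC class are argued against, since the median was 4.03 without clusters 10 and 15. RNA of other cell types is argued against as well: the highest level in any other KIC cluster exceeded the myofiber level by a median log2 of only 0.35 [-1.86 to 1.33], below the 4-fold it would need, and Myog, Gadd45a and Sln were lower in every other KIC cluster than in KIC myofiber nuclei, although Ncam1 was higher in some. More open promoters may take part, with the list at percentile 99.5 of random promoter lists, but the interval of that promoter median (0.23 [-0.14 to 1.09]) includes 0. Whether loss of nerve contact, the tumour or the library gives the pattern was not tested.

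Myofiber RNA was present in control nuclei of cluster 2, with Ttn at 14483 CPM against 330.1 CPM in KIC nuclei. Free RNA in all droplets is argued against, because the median over nuclei of the Ttn CPM was 0.0238 of the mean and 48.2% of these nuclei held no Ttn UMI. The same value of 0.0238 is what myofiber nuclei caught together with some of these nuclei would give. Nuclei above the median depth had a mean of 12269 CPM against 2375 CPM in the others, as doublets could give, and doublet removal took 3.28% of control nuclei. No biological explanation was tested.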

How the results depend on the processing

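The single doublet rules, the shared clusters, the left-out junction clusters and the removal of free RNA were chosen after the data were seen. No paired analysis was possible because each group is a single pooled library, both carry replicate number 1, and the values come from no test. Counting depth sets a floor of 0.283 and 0.188 CPM in the myofiber class, and members of lists under 20 UMIs were not read. The alternative of nuclei with a Y-linked UMI and no Xist was not run, since neither library held such myofiber nuclei. Tafa4 gave no value without the junction clusters.

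Of 26 list medians, all stayed inside their intervals and kept their sign with no doublets removed, at resolution 1.0, with the highest scores removed in both libraries and in nuclei with an Xist UMI. With median-of-ratios scaling 23 stayed inside and 25 kept their sign, and oxidative phosphorylation moved to -0.61. Signs were kept by 25 of 26 with at least 1000 genes, 25 of 26 with a single score threshold, 25 of 26 with the mean of per-nucleus CPM, 24 of 26 without the junction clusters, 26 of 26 with free RNA taken out, 23 of 25 with thinning, 24 of 25 with members of at least 100 UMIs and 24 of 25 in nuclei led by Myh4; the others changed sign. In nuclei led by Myh1, which keep myosin RNA by construction, fast sarcomere genes reversed to 0.19 and the unfolded protein and integrated stress response to -0.055, and 19 of 23 list medians kept their sign. The 23 named genes measured there kept their sign, but only 3 stayed inside their interval: Pxdn moved from 7.09 to 1.15, Hamp2 from 5.82 to 2.06 and Gdap1 from -3.37 to -0.17. In the shared clusters 5 and 7 oxidative phosphorylation moved to -0.051, fatty acid genes reversed to 0.082 and Clstn2 reversed to 0.53, while 22 of 25 list medians and 20 of 21 named genes kept their sign. Only 2 of these genes stayed inside their interval there, and Enpp3 moved from 8.18 to 2.27. There denervation-responsive genes stood at 1.83, proteasome subunits at 0.69, glycolysis at -0.68 and calcium handling at -0.35. For these moved and reversed values the cause was not tested.

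The KIC myofiber share of 78.8% moved to 72.6% with no doublets removed, 84.0% with at least 1000 genes and 73.5% with the highest scores removed in both. The control share of 55.3% moved to 63.0% with a single score threshold and 77.9% when each nucleus was named by its highest marker mean. With at least 5 myosin UMIs the KIC share led by Myh7 moved to 0%. The cause was not tested for these either. Of the 24 named genes all kept their sign under median-of-ratios scaling, thinning and the mean of per-nucleus CPM, with 21, 10 and 17 inside their interval. They also kept it with free RNA taken out (17 of 24 inside), in nuclei led by Myh4 (14 of 24), with a single score threshold (21 of 24) and without the junction clusters (20 of 23). With free RNA taken out Pakap moved from 6.63 to 10.75 [8.27 to 16.05], on 1 control UMI. Runx1 moved from 5.86 and Frmd5 from 7.72 to 10.51 and 10.51. Both were set to the floor of 3 counts in the control, since no control UMI was left. At 1000 UMIs per nucleus, Runx1 was in 2.70% of control cluster 2 nuclei and 0.655% of control myofiber nuclei. The RNA taken out can thus include RNA of cluster 2 itself, and the larger ratios follow from the subtraction. Without the junction clusters Kcnh7 moved from -3.84 to -0.26, Ankrd1 from 6.73 to 9.19 and Runx1 to 6.63, and the cause was not tested. All 10 named genes of cluster 2 kept their sign with no doublets removed, 5 of them inside their interval. Of 6 promoter medians 5 kept their sign within 2000 bp, and all 6 stayed inside their interval there and at 50% overlap.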

Other observations

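The split of KIC nuclei by cluster and the test of Trim63 and Fbxo32 nuclei were chosen only after the results were seen. Among KIC nuclei of clusters 3 to 6, Trim63 and Fbxo32 stood highest in cluster 3 and Runx1, Ncam1, Myog and Gadd45a in cluster 4. Cluster 3 (1122 KIC nuclei) had Trim63 at 15068 CPM and Fbxo32 at 12944 CPM, with Runx1 at 68.6 and Myh4 at 24.3 CPM. Cluster 4 (967 KIC nuclei) had Trim63 at 1872 and Fbxo32 at 2592 CPM, with Runx1 at 1104, Ncam1 at 1140.3, Gadd45a at 362 and Myh4 at 2776 CPM. The summed proteasome subunit RNA was 5643 CPM in cluster 3 and 2655 CPM in cluster 4. Their median depths were 3294 and 6425 UMIs and 3562 and 9510 peak counts. Whether these are nuclei of different animals of the pool could not be separated.

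Values of the other gene lists in myofiber nuclei follow, and the stress response, circadian, dystrophin, polyamine and endothelial lists lay inside the middle 95% of random lists. Myogenic factor genes were higher in KIC, with Myf6 at 3.33 [3.17 to 3.50] and Myod1 at 1.51 [1.22 to 1.80] (6 of 8 list members higher, 5 relative to the shift, median 1.10 [-0.71 to 3.33], percentile 99.5). Stress response genes had 7 of 9 members higher and 1 lower, but 4 and 2 relative to the shift, among them Atf4, a master regulator of the integrated stress response, at 1.77 [1.55 to 1.99], with a median of 0.59 [0.096 to 1.07] at percentile 91.4. In the insulin, IGF and mTORC1 list 10 of 16 were higher and 5 lower, or 8 and 6 relative to the shift, with Igf1r at 1.17 [1.09 to 1.24] and Irs1 at -0.93 [-1.001 to -0.87], and the median was 0.55 [-0.36 to 1.17] at percentile 97.9. Of 16 circadian clock genes 12 were higher and 1 lower, or 8 and 1 relative to the shift, with Nr1d1 at 2.60 [2.15 to 3.09] and Arntl at -0.26 [-0.32 to -0.20], and the median was 0.42 [0.18 to 1.32] at percentile 89.9. The dystrophin complex list had Utrn at 1.88 [1.76 to 2.000] and Lama2 at -1.80 [-1.85 to -1.75] and a median of 0.12 [-1.32 to 0.95] at percentile 59.8, which flips to -0.14 relative to the shift. Polyamine genes had Odc1, the rate-limiting enzyme, at 1.86 [1.55 to 2.18] and Smox at -2.02 [-2.22 to -1.82] and a median of -0.10 [-1.24 to 1.44] at percentile 5.64, which flips to 0.26 with thinning. Of 16 measured collagen and matrix genes 9 were lower and 4 higher, with Col5a3 at 2.51 [2.20 to 2.84] (percentile 0). The immediate early list lay at percentile 100, with Nr4a1 at -1.57 [-1.68 to -1.45]. Of 4 endothelial genes 1 was higher and 1 lower (median -0.24, percentile 10.2), and of 3 measured cell cycle genes 1 was higher, Pcna at 1.38 [0.60 to 2.25].

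KIC myofiber nuclei were also split by their Trim63 and Fbxo32 UMIs, to ask whether denervation-responsive RNA sits in the same nuclei. A UMI of Runx1, Ncam1, Myog, Chrna1, Gadd45a or Sln was present in 7.74% (6.02 to 9.76) of the 840 KIC nuclei with most Trim63 and Fbxo32 UMIs and in 53.5% (50.01 to 56.9) of the 840 with fewest, a ratio of 0.145. This decides nothing beyond the split by cluster, since the genes and bounds were chosen after that split had been seen. No adult myosin UMI was found in 96.9% and 23.7% of these nuclei. Nuclei were thinned to 1000 UMIs, of which Trim63 and Fbxo32 took at most 61.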
